A study of Rattus norvegicus with 10 samples.

How the data were processed

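Messenger RNA was measured by sequencing in 10 rat liver libraries, 5 from offspring of dams on a normal diet and 5 from offspring of dams fed 30% fewer calories during gestation. The labels call the material hepatocytes of a cell line, whereas the series' design text calls it liver tissue; liver is used below. Sex, age, litter, feeding state, time of collection and sequencing batch are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIpure and libraries were made with an NEBNext Ultra kit and sequenced on an Illumina NovaSeq instrument. Base calls were converted with bcl2fastq, trimmed with fastp and counted with HTSeq on the rat build rn7, per the submitters' processing notes. The series' design text adds a Q30 quality filter and alignment with HISAT2. Versions, gene annotation and the strand setting of the counting step are not given in the sources used here.

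The deposited table holds 12555 genes, each with a symbol or an Ensembl identifier, and 1 column per library, so no replicates were pooled. Per the file headers, the raw count columns hold the authors' counts per gene, which are whole numbers without scaling. The FPKM columns, per the file headers, hold the authors' length-scaled and depth-scaled fragment values. The library depth they imply differed from the total counts by −0.0491% to 0.123%. The deposited fold change is the authors' ratio of restricted over normal diet, per the file headers. The deposited log2 fold change is the log2 of that ratio. The deposited p-value and adjusted p-value come from the authors' own differential test, whose tool is not given in the sources used here. Their adjusted p equalled a Benjamini-Hochberg adjustment recomputed over the genes of the table. Per the series' design text, the authors called a gene changed at p below 0.05 with an absolute log2 fold change above 1. The authors' filter that limits the table to these genes is not given in the sources used here. Gene names were taken from the table itself, and no coordinates are printed because the annotation at hand was of another build.

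From the counts, log2 fold changes of restricted minus normal diet were fitted with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr (minimum count 10) kept 12367 genes and removed 188. Libraries were scaled with TMM factors, dispersions were estimated robustly, and the quasi-likelihood test was two-sided with Benjamini-Hochberg adjustment over all genes tested. Intervals are 95% intervals of the fit. CPM values are counts scaled to the TMM-adjusted library sizes and are given as mean ± SD over 5 libraries. A count of 0 was read against a floor of 3 counts per library, and floors cover counting error only. Total counts ran from 14936156 to 22104957 per library. For every pair of libraries in a group the chi-square per degree of freedom was at least 21.2, so the spread between libraries was larger than counting error. The p-values measure the spread between these libraries; the labels do not say that each came from a separate animal or litter.

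Choices of groups, tests, 38 gene lists and named genes were made before the data were examined. Named are the 12 genes with the largest change in each direction among those past adjusted p 0.05 with a mean log2 CPM of at least 0 and a gene symbol, 18 fixed genes, and up to 4 members of each list with the smallest p. Any other gene is said to have been chosen after its values were seen. Lists with at least 4 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 35 lists that qualified. Beside it stand camera with an estimated correlation and fry, whose directional p tests whether a list's genes move on balance to the same side. A list score is the mean log2 CPM of its members in a library, given as the difference from the normal diet mean. List scores and the difference between periportal and pericentral scores were compared with two-sided exact permutation tests of 5 against 5 libraries, whose smallest p is 0.00794. Members of the cytochrome P450, carboxylesterase and globin families resemble each other in sequence, and how reads shared by several genes were counted is not given in the sources used here.

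Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 1 CPM in 5 libraries, the replicate number as a block, log2 CPM of the Y-linked gene Kdm5d as a covariate, and each library left out in turn. Fits on subsets of libraries, permutation tests of list scores other than zonation, Kdm5d as a covariate in the list tests, and an estimated correlation in the list tests of that fit, of the subsets and of the fits without a library, were added after the data were seen. Subset fits kept the genes tested with all 10 libraries. Counts of changed genes and lists were also compared with 100 seeded splits of the libraries into 5 and 5. Calls were tested on simulated counts of 12300 genes with known changes, 5 libraries against 5. There, edgeR found 28.4% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 95.2% of those changed 4-fold, and 5.51% of its calls were unchanged genes. DESeq2 found 34.3%, 73.1% and 96.8%, with 17.4% of its calls unchanged. Limma-voom found 26.9%, 62.7% and 95.2%, with 3.23% of its calls unchanged. Camera with either correlation called both changed lists and no unchanged list, and fry called both and 1 unchanged list. Genes were simulated independently of each other, so this does not test calls on lists whose members vary together. In the real data the estimated correlation was 0.609 for cholesterol synthesis and 0.933 for the interferon response. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the comparison.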

Results

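RNA sequencing measured gene expression in 10 rat liver libraries, 5 from offspring of dams on a normal diet (normal 1 to 5) and 5 from offspring of dams under 30% calorie restriction in pregnancy (restricted 1 to 5). Total counts per library ran from 14936156 to 22104957 over 12555 genes. Across genes, correlations of log2 CPM were 0.972 to 0.981 between normal libraries, 0.941 to 0.978 between restricted libraries, and 0.940 to 0.972 between the groups.

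The Y-linked gene Kdm5d (ENSRNOG00000060496), which encodes a histone demethylase, had 319, 392, 383, 358 and 280 counts in normal 1 to 5. It had 0 counts in restricted 1 to 4 and 309 in restricted 5. A count of 0 allows up to 0.136 to 0.199 CPM in those 4 libraries. Cyp2c13, a cytochrome P450 known to be expressed mainly in livers of adult male rats, had 154 to 2203 CPM in the normal libraries, 1035 CPM in restricted 5 and 1.29 to 8.29 CPM in restricted 1 to 4. Cux2, a transcription factor known to be expressed mainly in female rodent liver, had 1.07 to 5.48 CPM in the normal libraries, 1.74 CPM in restricted 5 and 13.6 to 24.0 CPM in restricted 1 to 4. Cyp2c12, a cytochrome P450 known to be expressed mainly in livers of adult female rats and chosen after its values were seen, followed this division except in normal 1, with 3049 CPM there, 497 to 1283 CPM in the other normal libraries, 298 CPM in restricted 5 and 2198 to 2714 CPM in restricted 1 to 4. By Kdm5d, Cyp2c13 and Cux2, restricted 1 to 4 looked female, and restricted 5 and the normal libraries looked male. The labels give no sex, and the division by Kdm5d runs with the maternal diet in 9 of the 10 libraries.

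**Figure D1:**
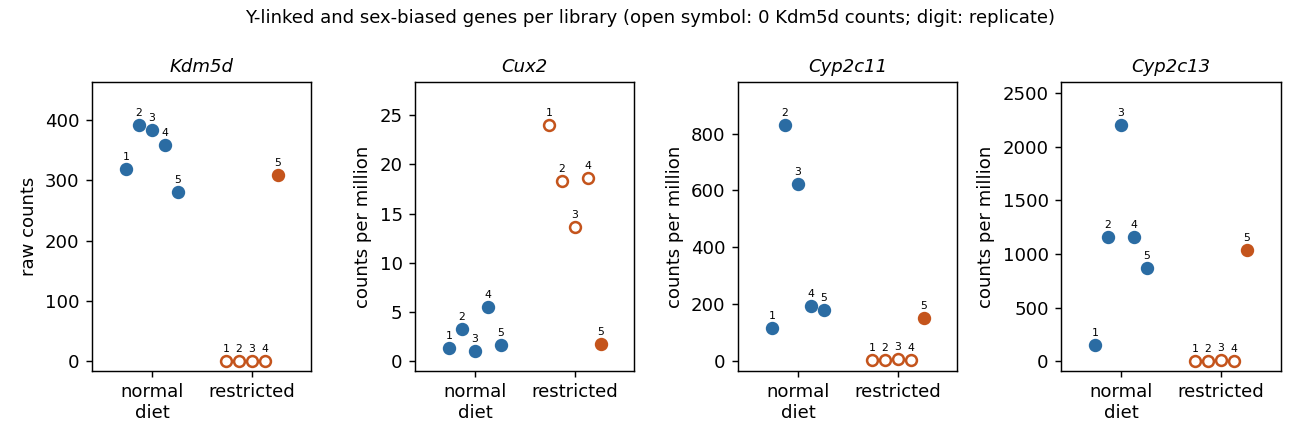
Raw counts of Kdm5d and CPM of Cux2, Cyp2c11 and Cyp2c13 in each library, by maternal diet; each point is a library, digits are replicate numbers and open symbols mark 0 Kdm5d counts. Restricted 5 sits among the normal diet libraries for Kdm5d with 309 counts and for Cyp2c13 with 1035 CPM.

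The comparison of the diets asks how the liver of offspring born after maternal restriction differs from that of offspring of normally fed dams. Such restriction is a model of birth small for gestational age. In this comparison the likely sex runs with diet, since only restricted 5 of the restricted libraries had Kdm5d counts. In the restricted group, genes of fatty acid oxidation were higher and genes of fatty acid and cholesterol synthesis were lower (each list adjusted p = 0.441 with an estimated correlation). Fgf21 (ENSRNOG00000020990), which encodes a liver hormone released in fasting, rose 7.21-fold from 6.06 ± 1.54 to 43.7 ± 19.2 CPM (SD, n = 5 per group). Acly (ENSRNOG00000016924), which makes acetyl-CoA for lipid synthesis, fell from 413 ± 63.0 to 127 ± 47.4 CPM (SD, n = 5 per group). Igf1 (ENSRNOG00000004517), a growth factor made in liver under growth hormone, fell from 1359 ± 240.5 to 636 ± 174 CPM (SD, n = 5 per group). All 5 restricted libraries lay on the same side of the normal mean for each of these 3 genes, and their adjusted p were 0.00266, 0.00527 and 0.00888 in edgeR.

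Of 12367 genes tested with the edgeR quasi-likelihood test, 506 passed a Benjamini-Hochberg adjusted p of 0.05, 231 higher and 275 lower in the restricted group. At an unadjusted p of 0.05, 2484 genes passed, and 364 of them met the authors' fold rule (223 higher, 141 lower). With Kdm5d as a covariate 121 genes passed, 30 of them among the 506, and DESeq2 called 1049, 503 of them among the 506. Leaving out 1 library at a time gave 213 to 470 genes, with 265 without normal 3, 226 without normal 4, 213 without normal 5, 231 without restricted 2 and 301 without restricted 4.

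Of 171 named genes, 70 passed the test, and 28 of these passed in each of the 10 fits that left out a library. Fgf21, Cry1, Acly and Gbe1 passed in all 20 alternative fits. With Kdm5d as a covariate 7 of these 70 passed: Fgf21, the clock gene Cry1, Acly, the glycogen branching enzyme Gbe1, the stress-response gene Gadd45b, the kinase Ptk6 and Bckdhb of branched-chain amino acid breakdown, at adjusted p of 0.0284 to 0.0482. That fit also called 4 named genes that did not pass without the covariate: the immediate early gene Klf6 (adjusted p 0.0328), the macrophage genes Csf1r (0.0390) and Cd5l (0.0420), and Cd8a of T cells (0.0482). The diet change in that fit rests mainly on restricted 5, the only restricted library with Kdm5d counts. Csf1r and Cd5l changed by 1.55 and 1.36 (log2) with the covariate, and by 1.52 and 1.35 in restricted 5 against the normal libraries. Of the 70, limma-voom did not call 14 and the fit with the replicate number as a block did not call 30. Without normal 5, Gadd45b, Ptk6 and Bckdhb had adjusted p of 0.0918, 0.0584 and 0.0581. Gadd45b also missed the threshold without normal 1, 2, 3 or 4 or restricted 4, and Ptk6 without normal 4 or restricted 2 or 4.

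**Figure D2:**
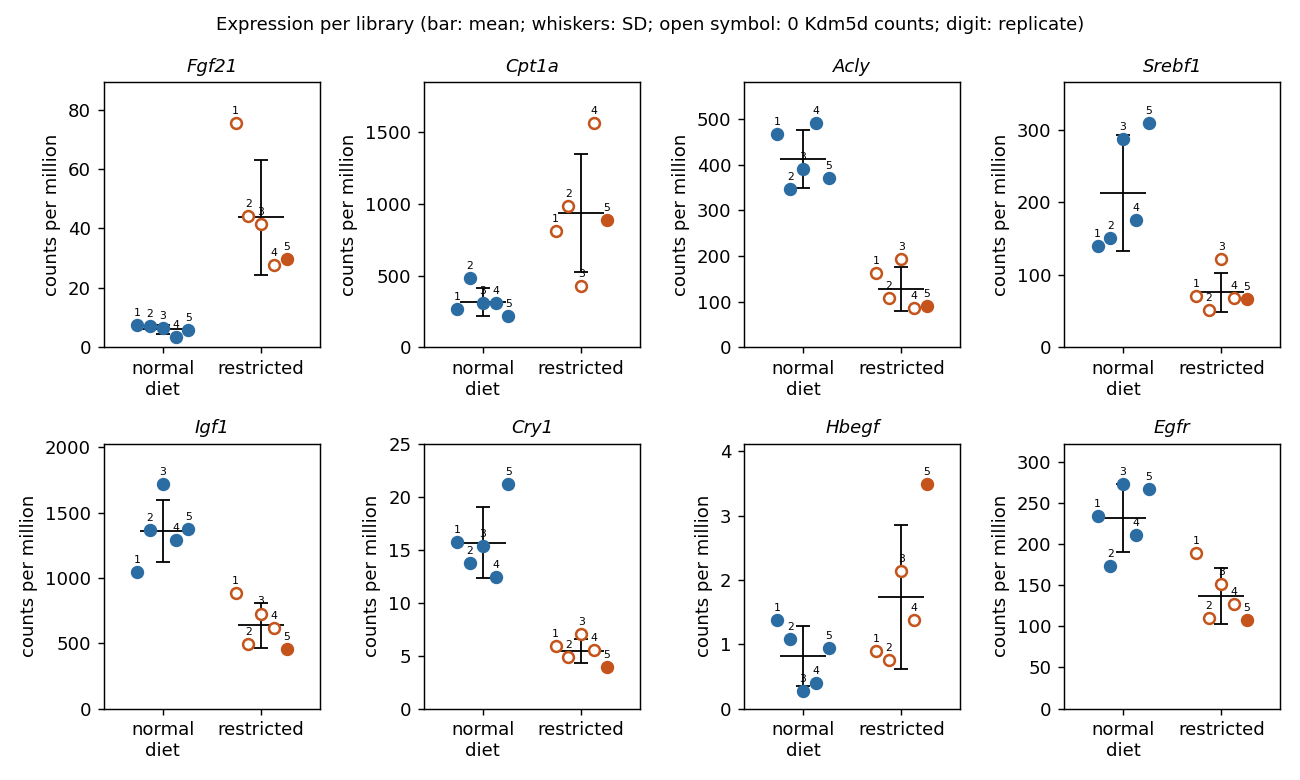
CPM of 8 named genes in each library, by maternal diet, with the mean (bar) and SD (whiskers) of 5 libraries; digits are replicate numbers and open symbols mark 0 Kdm5d counts. Fgf21 and Cpt1a were higher and Acly, Srebf1, Igf1, Cry1 and Egfr lower in the restricted group past adjusted p 0.05, and Hbegf did not pass (adjusted p 0.266).

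Fatty acid oxidation and ketogenesis genes were higher in the restricted group, with 11 of 28 tested members past the test, all higher, and 18 when adjusted over the list alone. The list's median log2 fold change was 0.62 (camera adjusted p 3.33e-11, adjusted p = 0.441 with an estimated correlation, fry 0.0247). Cpt2, of the carnitine shuttle that carries fatty acids into mitochondria, rose by 0.90 ± 0.13 (log2, SE; adjusted p 0.00553). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 1.99 ± 0.32 (adjusted p 0.0106), and the transcription factor Creb3l3 rose by 0.82 ± 0.12 (adjusted p 0.00557). Cpt1a, the rate-limiting step of the shuttle, rose from 317 ± 98.8 to 936 ± 411 CPM (SD, n = 5; adjusted p 0.024), although its adjusted p reached 0.0640 without normal 5, and it also missed the threshold without normal 1 (0.0535), normal 3 (0.0630), normal 4 (0.0631) and restricted 2 (0.0608). Ppara, the receptor that drives these genes, had a log2 fold change of 0.76 ± 0.25 that did not pass (adjusted p 0.114).

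Fatty acid and triglyceride synthesis genes were lower, with 7 of 20 tested members past the test, all lower, and with 1 higher and 11 lower when adjusted over the list alone. The median log2 fold change was −0.90 (camera adjusted p 9.42e-08, adjusted p = 0.441 with an estimated correlation, fry 0.0307). Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, fell from 178 ± 20.0 to 79.5 ± 22.8 CPM (SD, n = 5; adjusted p 0.00602). Srebf1, the transcription factor that activates these genes, fell from 212 ± 80.1 to 75.4 ± 26.7 CPM (adjusted p 0.0229). Fasn, fatty acid synthase, had a log2 fold change of −1.96 ± 0.50 that did not pass (adjusted p 0.0665). Me1, which makes NADPH for the pathway, changed by −0.94 ± 0.19 (adjusted p 0.0215, and 0.0598 without normal 4). For Srebf1 the adjusted p was 0.0528 without normal 3, 0.0508 without normal 5, 0.0548 without restricted 2, 0.0601 without restricted 4 and 0.0501 without restricted 5.

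Cholesterol synthesis genes were lower, with 5 of 22 tested members past the test, all lower, and 19 when adjusted over the list alone. The median log2 fold change was −0.75 and all 22 members were negative (camera adjusted p 3.07e-13, adjusted p = 0.441 with an estimated correlation, fry 0.0390). Fdft1, squalene synthase, fell from 292 ± 46.6 to 158 ± 21.3 CPM (SD, n = 5; adjusted p 0.00555). Dhcr7, the last step to cholesterol, fell from 265 ± 86.1 to 125 ± 15.3 CPM (adjusted p 0.0088), and Nsdhl fell from 517 ± 78.5 to 314 ± 42.7 CPM (adjusted p 0.0109).

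Of 35 lists tested, 9 passed camera with the preset correlation, 4 higher and 5 lower, and 4 passed with fry. With an estimated correlation camera called 0 of 35, and 3 had an unadjusted p under 0.05. The list scores of all 5 restricted libraries lay outside the range of the normal libraries for each of these 3 lipid lists and for glycolysis, at the smallest exact permutation p this design allows (two-sided, 0.00794, and 0.0694 adjusted over the lists). In restricted 5, the restricted library with Kdm5d counts, the median changes were 0.71 for oxidation, −1.38 for fatty acid synthesis and −1.07 for cholesterol synthesis, against 0.63, −0.77 and −0.69 in the other 4. With Kdm5d as a covariate the lists had adjusted p of 7.69e-06 for oxidation, 1.22e-10 for fatty acid synthesis and 7.22e-11 for cholesterol synthesis, and of 0.564, 0.233 and 0.437 with an estimated correlation. Camera with an estimated correlation also called 0 of 35 lists in each fit without a library.

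Growth hormone and IGF axis genes included 1 member that rose and 3 that fell of 16 tested, or 1 and 4 when adjusted over the list alone. Igf1 changed by −1.09 ± 0.19 (log2, SE; adjusted p 0.00888). Igfals, which carries IGF1 in blood, fell from 182 ± 50.3 to 71.9 ± 23.7 CPM (SD, n = 5; adjusted p 0.0244). Igfbp2, an IGF binding protein, rose from 37.4 ± 26.1 to 185 ± 58.4 CPM (adjusted p 0.0408), and Stat5a, of growth hormone signalling, changed by −0.57 ± 0.13 (adjusted p 0.0260). Igf2, a fetal growth factor, had 0.933 ± 0.204 and 0.837 ± 0.558 CPM (adjusted p 0.910). The list as a whole did not pass (camera adjusted p 0.156, and adjusted p = 0.589 with an estimated correlation), but it passed as lower with Kdm5d as a covariate (adjusted p 0.0381, median log2 fold change −0.52, and adjusted p 0.343 with an estimated correlation). With 1 library left out, adjusted p reached at most 0.0632 for Igfals and 0.110 for Igfbp2, both without normal 5, and 0.0737 for Stat5a, also without normal 5. Igfals missed the threshold also without normal 3 or 4 or restricted 2 or 4, Stat5a without normal 2, 3 or 4 or restricted 2 or 4, and Igfbp2 without any library except normal 1 or 2.

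Hbegf (ENSRNOG00000018646), the EGF receptor ligand that the series title names, had low counts and did not pass the test. It had 21, 17, 4, 6 and 14 counts in the normal libraries and 20, 14, 31, 21 and 56 in the restricted ones, or 0.813 ± 0.468 and 1.73 ± 1.12 CPM (SD, n = 5 per group). Its log2 fold change was 1.07 ± 0.51 (SE; 95% interval −0.04 to 2.18; p 0.0582, adjusted p 0.266 in edgeR), with 4 of 5 restricted libraries above the normal mean. Egfr, its receptor, fell from 231 ± 41.1 to 137 ± 33.8 CPM (SD, n = 5; adjusted p 0.0306). Its adjusted p stayed past the threshold when normal 2, restricted 1 or restricted 3 was left out, and not for the other 7 libraries, reaching 0.0830 without normal 5. Of 11 tested EGF receptor ligands and receptors, Egfr alone passed, over all genes and when adjusted over the list alone (camera adjusted p 0.518). The restricted library with the highest Hbegf, restricted 5, is the one with Kdm5d counts, and without it the log2 fold change was 0.64 (adjusted p 0.519).

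Glycolysis genes were lower, with 1 of 17 tested members past the test, or 4 lower when adjusted over the list alone, a median log2 fold change of −0.10 and a mean of −0.30. The list score differed by −0.331, and fry gave an adjusted p of 0.0243, its smallest over the lists. Camera gave an adjusted p of 0.0179 (adjusted p = 0.441 with an estimated correlation), and 0.179 with Kdm5d as a covariate. Pklr, liver pyruvate kinase, fell from 423 ± 64.8 to 147 ± 68.1 CPM (SD, n = 5; adjusted p 0.0172, and 0.0565 with the replicate block). In the list of gluconeogenesis and glycogen, 2 of 12 members fell, also 2 when adjusted over the list alone. They were Gbe1, from 202 ± 21.1 to 101 ± 22.8 CPM (adjusted p 0.00553), and Pygl, glycogen phosphorylase, with a log2 fold change of −0.72 ± 0.15 (adjusted p 0.0191, 0.0525 without normal 5 and 0.0508 without restricted 2). Pck1, of gluconeogenesis, had a log2 fold change of 0.54 ± 0.34 (adjusted p 0.397). The gluconeogenesis and glycogen list did not pass (camera adjusted p 0.337), but it passed as lower with Kdm5d as a covariate (adjusted p 0.0427, and 0.343 with an estimated correlation).

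The list oxidative phosphorylation, nuclear encoded, had a median log2 fold change of −0.14, with 2 of 19 tested members past the test, both lower, also 2 when adjusted over the list alone. Camera gave an adjusted p of 0.0183 (adjusted p = 0.589 with an estimated correlation), and 0.0802 without restricted 1 and 0.0996 without restricted 2. It was 0.0819 with Kdm5d as a covariate and 0.234 with only restricted 1, 3 and 4. Cox5a, of respiratory complex IV, changed by −0.33 ± 0.09, and Ndufs8, of complex I, by −0.31 ± 0.08 (log2, SE; both adjusted p 0.0494). With 1 library left out these reached 0.129 and 0.128, both without normal 4, and both missed the threshold without any other library except restricted 4, where Cox5a passed.

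Circadian clock genes moved both ways: 2 of 17 tested members rose and 2 fell, and the same numbers passed when adjusted over the list alone. Cry1, a repressor of the clock, fell from 15.7 ± 3.37 to 5.45 ± 1.16 CPM (SD, n = 5; adjusted p 0.00251), and Per2, another repressor, changed by −1.51 ± 0.37 (adjusted p 0.0403). Nr1d2 rose from 22.1 ± 5.34 to 46.1 ± 10.2 CPM (adjusted p 0.00888), and Nr1d1 changed by 2.13 ± 0.43 (adjusted p 0.0277); both encode REV-ERB repressors of the clock. The list's median was −0.06 with a mean of 0.04, and camera gave an adjusted p of 0.548. The time of collection is not given, and with 1 library left out adjusted p reached 0.114 for Per2 without normal 5 and 0.0703 for Nr1d1 without normal 3. Per2 passed without normal 1 or 2, and Nr1d1 without normal 2 or 5 or restricted 1 or 3.

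Cell cycle genes were lower in the restricted group, with 2 of 24 tested members past the test, both lower, and 3 when adjusted over the list alone. All 24 members were negative, with a median log2 fold change of −0.56 (camera adjusted p 9.42e-08, adjusted p = 0.589 with an estimated correlation). Rrm2 and Tyms, which make nucleotides for DNA synthesis, changed by −1.98 ± 0.44 (adjusted p 0.0381) and −0.46 ± 0.11 (adjusted p 0.0408). Mki67, a marker of dividing cells, had 47.0 ± 7.99 and 34.9 ± 17.2 CPM and did not pass (adjusted p 0.539). The list score was −1.69 in restricted 4 against −0.75 to −0.09 in the other restricted libraries. With 1 library left out, adjusted p reached 0.0891 for Rrm2 without restricted 2, which passed without normal 2, restricted 1 or restricted 4, and 0.0973 for Tyms without normal 3, which passed without normal 4.

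Kupffer cell and macrophage markers, of the resident macrophages of liver, were higher in the list test, although 0 of 13 members passed in edgeR on their own or when adjusted over the list alone. All 13 were positive, with a median log2 fold change of 0.67 (camera adjusted p 0.000149, adjusted p = 0.589 with an estimated correlation). Of the 13, 7 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. With Kdm5d as a covariate 3 were called higher, and the median log2 fold change was 1.36, near the 1.35 of restricted 5 against the normal libraries. Csf1r, the macrophage growth factor receptor, had 102 ± 14.3 and 170 ± 80.1 CPM (SD, n = 5; adjusted p 0.169). The list score was 0.90 in restricted 2 and 1.31 in restricted 5, against 0.00 to 0.41 in the other restricted libraries.

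T, NK and B cell markers had a median log2 fold change of 1.08 over 8 tested members, of which 0 passed in edgeR, 1 rose when adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Camera gave an adjusted p of 0.0183 (adjusted p = 0.589 with an estimated correlation), and 0.0988 without restricted 5. With Kdm5d as a covariate 1 member was called higher, and the median log2 fold change was 2.21, near the 2.13 of restricted 5 against the normal libraries. Cd74, which serves antigen presentation, had 95.6 ± 21.2 and 179 ± 60.1 CPM (SD, n = 5; adjusted p 0.0543). The score was 1.34 in restricted 2, 2.05 in restricted 5 and 1.01 in restricted 4. Interferon response genes had scores of 2.32 in restricted 2, 2.19 in restricted 5 and −1.60 to −0.67 in restricted 1, 3 and 4, and 0 of 18 passed in edgeR, 0 when adjusted over the list alone, 2 at an unadjusted p of 0.05 and 0 in DESeq2 and limma-voom (camera adjusted p 0.239). With only restricted 1, 3 and 4, the list tests gave adjusted p of 0.0971 for Kupffer cell and macrophage markers, 0.334 for lymphocyte markers and 1.59e-05, now lower, for the interferon response (0.556 with an estimated correlation). With Kdm5d as a covariate the interferon response was called higher instead (adjusted p 1.57e-06, median log2 fold change 2.07), and so it was without restricted 4 (adjusted p 0.00727), but with an estimated correlation these were 0.668 and 0.625.

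The erythroid markers included 1 of 6 tested members that rose, also 1 when adjusted over the list alone. Ahsp, the chaperone of alpha globin, had 0.673 ± 0.235 and 1.95 ± 0.934 CPM (SD, n = 5; adjusted p 0.0408, and up to 0.104 without normal 4, passing without restricted 1 or 5). The median log2 fold change was 0.70 (camera adjusted p 0.0212, adjusted p = 0.589 with an estimated correlation), and the call was lost without normal 1 (0.0815), restricted 2 (0.104) or restricted 3 (0.0957). With Kdm5d as a covariate it was also lost (adjusted p 0.840).

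**Figure D3:**
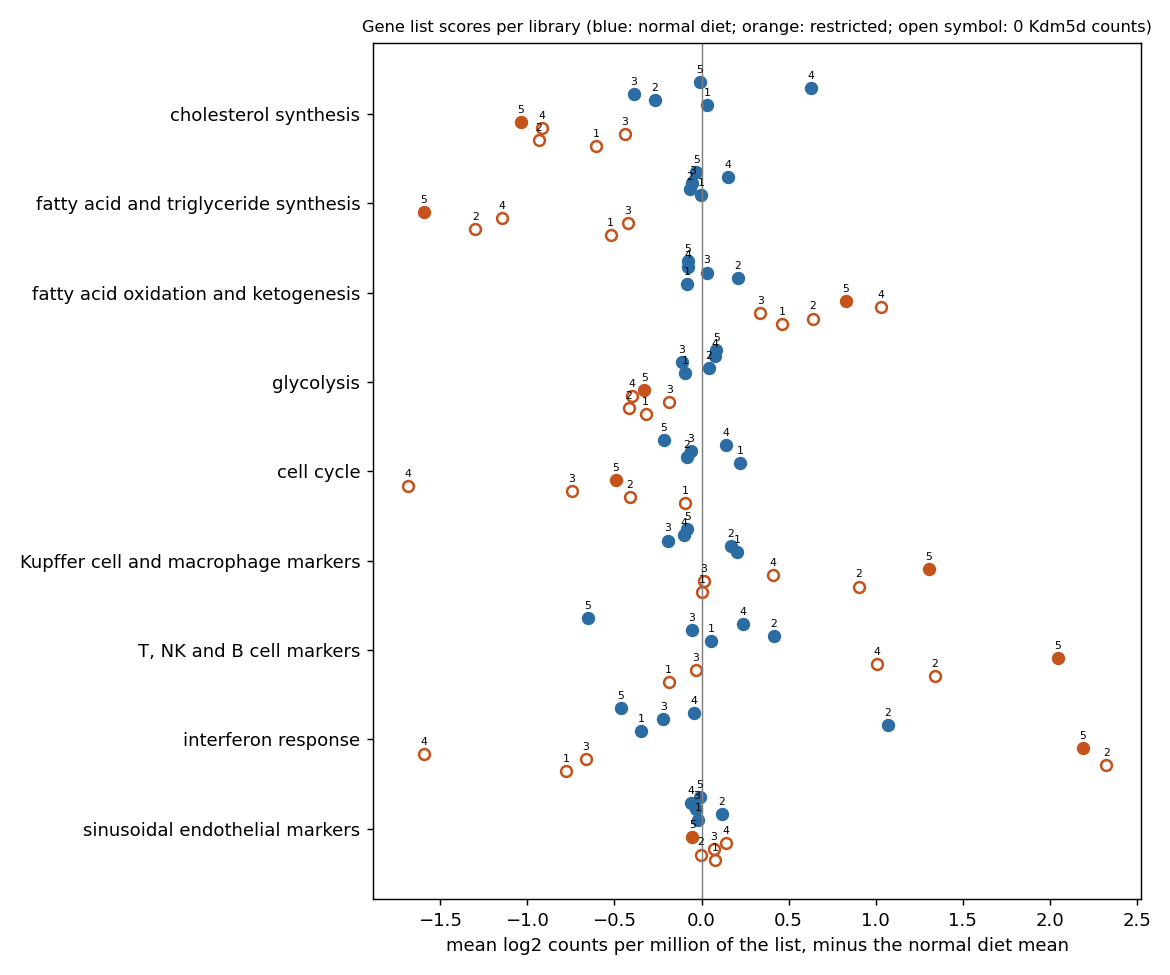
Mean log2 CPM of 9 gene lists in each library, relative to the normal diet mean; blue points are normal diet, orange points restricted, digits are replicate numbers and open symbols mark 0 Kdm5d counts. The 3 lipid lists separate the groups, while the macrophage score is 0.90 and 1.31 in restricted 2 and 5 and the endothelial scores lie between −0.06 and 0.14.

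Markers of sinusoidal endothelium had scores of −0.06 to 0.14 in all 10 libraries, with 0 of 12 members past the test in edgeR, 0 when adjusted over the list alone, 2 at an unadjusted p of 0.05 and 0 in DESeq2 and limma-voom (camera adjusted p 0.399). Hepatocyte markers had 1 of 13 members past the test, also 1 when adjusted over the list alone: Ttr, which carries thyroid hormone, changed by −0.71 ± 0.18 (adjusted p 0.0497, and up to 0.131 without normal 5, passing without normal 1 or restricted 3). Alb, albumin, had a log2 fold change of 0.05 ± 0.17 (adjusted p 0.907).

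Zonation of hepatocyte genes between the portal and central ends of the lobule did not differ detectably. The periportal score minus the pericentral score was 1.62 ± 0.26 in the normal and 1.52 ± 0.34 in the restricted libraries (SD, n = 5; difference −0.11, two-sided exact permutation p 0.619). The difference was 0.131 with medians over list members and 0.0139 without restricted 2. Of 12 periportal members 2 fell, or 3 when adjusted over the list alone, among them Cyp2f4, a cytochrome P450, from 56.3 ± 5.81 to 38.1 ± 5.40 CPM (adjusted p 0.0155). Of 12 pericentral members 1 fell, also 1 when adjusted over the list alone: Rhbg, an ammonium transporter, changed by −0.71 ± 0.16 (adjusted p 0.0296, and up to 0.0749 without normal 5, passing without normal 2 or 3 or restricted 1 or 5). Camera gave adjusted p of 0.399 for the periportal and 0.911 for the pericentral list.

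Among the genes with the largest changes, Ces2e (ENSRNOG00000011635), a carboxylesterase, rose from 1.79 ± 0.966 to 136 ± 83.6 CPM (SD, n = 5; adjusted p 0.0150), with 5.05 CPM in restricted 4. Its call was lost with limma-voom (adjusted p 0.227), the replicate block (0.101) and Kdm5d as a covariate (0.0797). With that covariate its log2 fold change was 5.83, against 6.24 without it. Gpat3, an acyltransferase of triglyceride synthesis, rose from 0.761 ± 0.203 to 10.8 ± 9.49 CPM (adjusted p 0.0088), with 27.2 CPM in restricted 4 and 3.18 to 9.71 CPM in the others. Its log2 fold change was 3.81, and 3.15 without restricted 4 (adjusted p 0.00189). Its call was lost with limma-voom (0.0717) and Kdm5d as a covariate (0.201), where the log2 fold change was 1.98. Hdc, which makes histamine, rose from 0.893 ± 0.374 to 5.24 ± 3.24 CPM (adjusted p 0.0088), and Qpct and Tox rose by 2.47 ± 0.36 and 2.42 ± 0.40 (log2, SE). The calls of Hdc, Qpct and Tox were lost with Kdm5d as a covariate (adjusted p 0.209, 0.153 and 0.295). Their log2 fold changes against the normal libraries were 1.67, 1.56 and 1.24 in restricted 5. In restricted 1 to 4 they were 2.70, 2.62 and 2.61. Clca2 (ENSRNOG00000013771) had 68, 214, 240, 74 and 211 counts in the normal and 2, 1, 0, 4 and 0 in the restricted libraries (adjusted p 0.0017). Fam111a, which encodes a protease, fell from 67.3 ± 36.5 to 2.77 ± 1.24 CPM (adjusted p 0.00329), and Nrep fell from 268 ± 80.8 to 44.6 ± 20.6 CPM (adjusted p 0.0088). The calls of Clca2, Fam111a and Nrep were also lost with the covariate (adjusted p 0.0544, 0.0964 and 0.202). Their log2 fold changes were −8.99, −4.41 and −2.04 with it, against −6.91, −4.57 and −2.59 without it. The other 16 of these 24 genes included Colq, Upp2 and Rab30, which rose, and Ca3, Aacs, Mst1r and the lipase gene Pnpla3, which fell; each of these 7 missed the threshold in at least 1 fit without a library, with adjusted p up to 0.110 for Pnpla3 without normal 3.

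In the deposited comparison of the authors, 479 genes met their rule of p below 0.05 with an absolute log2 fold change above 1, 323 of them higher and 156 lower. At an adjusted p of 0.05 their table held 1065 genes, 522 higher and 543 lower, and all 506 edgeR calls were among them. Of the 479 genes, 292 passed the authors' adjusted p and 145 passed the edgeR adjusted p. For Hbegf the table gave a log2 fold change of 1.08, a p of 0.0429 and an adjusted p of 0.212. Hbegf thus met the authors' rule of unadjusted p and fold, but not an adjusted p of 0.05. The authors' log2 fold changes differed from a DESeq2 fit of the same counts by at most 0.00577.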

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

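The counts over other splits of the libraries were planned, and every other test in this part was chosen after the result was seen.

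The division of the libraries by diet gave 506 genes past adjusted p. Of 100 splits of the 10 libraries into 5 and 5, only 1, the real one, gave as many, with 5 in the highest other split. A chance division of these 10 libraries is therefore unlikely to give this count. The splits cannot address differences between litters, which are not given. By the rule of unadjusted p and fold, also only 1 of 100 splits, the real one, gave as many, with 364 genes against 310 in the highest other split. The sex of the animals may account for part of these genes, since 4 of 5 restricted libraries had 0 Kdm5d counts, 5 of 6 sex-biased genes with a large change in those 4 lay nearer the normal level in restricted 5, and Kdm6a, an X-linked gene chosen after its values were seen, had 42.9 to 49.0 CPM in those 4 against 29.2 in restricted 5 and 24.3 to 30.6 in the normal libraries, and Cyp2c12, known as female-biased and also chosen after its values were seen, had 2198 to 2714 CPM in those 4 against 298 in restricted 5 and 497 to 1283 in the normal libraries other than normal 1, which had 3049. Genes were also called without restricted 5 and without 1 normal library at a time. Restricted 5 held a median share of 0.491 to 0.729 of their change, and the sign was the same for 78.0% to 91.9%. The libraries that picked these genes also set the size of the change, so a share below 1 can arise without any sex effect. With 1 restricted library that has Kdm5d counts, sex and maternal diet cannot be told apart for the 506 genes, and the diet itself stays open as an untested biological explanation.

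Lower lipid synthesis lists and a higher fatty acid oxidation list were seen in all 5 restricted libraries. A lower share of hepatocytes would lower the genes of all 3 lists together. The fatty acid oxidation score instead differed by 0.660 upward, so such a share cannot be the cause of that rise. The rise is part of the pattern itself, so it does not test whether such a share added to the lower synthesis lists. Hepatocyte markers differed by −0.108 (two-sided exact permutation p 0.190), against −0.787 for cholesterol synthesis and −0.997 for fatty acid synthesis. Sex could contribute, although in restricted 5 the smallest of the 3 list changes was 1.13 of that in the other 4; with Kdm5d as a covariate the lists had adjusted p of 7.69e-06 for oxidation, 1.22e-10 for fatty acid synthesis and 7.22e-11 for cholesterol synthesis (0.564, 0.233 and 0.437 with an estimated correlation), but that fit too rests on a single such library, and sex cannot be told apart from diet here. Time of day or feeding at collection cannot be told apart either, because the labels give neither, 4 clock genes passed adjusted p, and the fasting-induced gene Pdk4, chosen after its values were seen, lay outside the normal range in 4 of 5 restricted libraries. As for the number of lists, 34 of 100 splits gave as many as the 9 seen, with 15 in the highest other split, so chance cannot be excluded for that count, and maternal diet stays open for the lists.

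Macrophage and lymphocyte marker genes were high in restricted 2 and restricted 5, together with interferon response genes. Restricted 4 also lay above every normal library for both marker lists, with scores of 0.412 for macrophages and 1.01 for lymphocytes. Its interferon response score was −1.60, so the marker lists did not always rise together with that response. A lower share of hepatocytes would raise markers of all other cell types, but the gap between the macrophage and endothelial scores lay 6.19 SD of the normal libraries above their mean in restricted 2 and 9.28 in restricted 5, which argues against it as the whole cause. It may still add a part, since cholangiocyte markers had scores of 0.852 in restricted 2 and 0.631 in restricted 5, against −0.178 to 0.127 in the normal libraries, and hepatocyte markers −0.329 and −0.127, against −0.0991 to 0.119. Residual blood may add to the lymphocyte markers in restricted 2, whose erythroid score was 1.59, above all normal libraries, whereas it was 0.0681 in restricted 5, within their range, which argues against blood there. Of the 6 erythroid markers, all present in the normal libraries too, Hba-a2 was the most abundant, with 1967 CPM in restricted 2, 473 in restricted 5 and 625 to 1010 in the normal libraries, but restricted 3 had an erythroid score of 1.13 without a higher lymphocyte score (−0.0335). Maternal restriction cannot be told apart from differences between single livers, since the macrophage score differed with an exact permutation p of 0.0794 and the rise was carried by a part of the libraries.

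Of 170 groups of 5 libraries examined, 9 held a library far from the other 4, and chance gives about 5% of groups, or 1 in 20. Of these 9, 3 were in restricted 5. Restricted 1 had a total of 22.1 M counts, against 15.1 to 17.0 M in the other restricted libraries. Restricted 5 had 19.3 CPM of Kdm5d, against 0 in the other 4. The score of male-biased liver genes in restricted 5 was 0.540, against −4.07 to −3.57 in the other 4. The score of female-biased liver genes in restricted 5 was −0.785, against 0.924 to 1.31. Ces2e had 5.05 CPM in restricted 4, against 103 to 205 in the others. The circadian clock score was −0.195 in restricted 2, against 0.0723 to 0.0896. In normal 1 the unfolded protein and amino acid response score was 0.361, against −0.136 to −0.0685. In normal 2 the interferon response score was 1.07, against −0.464 to −0.0425, and the endothelial score was 0.118, against −0.0612 to −0.0102.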

How the results depend on the processing

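The fits on subsets of libraries, Kdm5d as a covariate in the list tests, and an estimated correlation in the list tests of these fits and of those without a library, were chosen after the data were seen. With RLE or upper-quartile scaling, limma-voom, no filter or the stricter filter, 450 to 516 genes passed adjusted p, sharing 430 to 503 with the 506. DESeq2 gave 1049 genes. On simulated counts 17.4% of its calls were unchanged genes, but that share depends on how many genes change and does not carry over to these 1049. The replicate number as a block gave 265 genes (242 shared). Of the 10 libraries, 4 were closest to their own number, and the correlations of same-number differences were −0.185 to 0.121. These values do not settle whether the numbers pair the samples. Kdm5d as a covariate gave 121 genes (30 shared) and 942 by the rule of unadjusted p and fold. The 6 libraries with Kdm5d counts gave 802 (149 shared) and 1046, with restricted 5 as the lone restricted library assumed to vary like the normal ones. Restricted 1, 3 and 4 with the normal libraries gave 365 (247 shared). With each library left out, 213 to 470 genes passed adjusted p and 316 to 493 met the other rule, which 320 to 423 met in the remaining alternatives. None of the 506 genes changed sign in these fits. The fits reuse the libraries from which the 506 were called, so keeping the sign was favoured by that choice. With restricted 5 and 1 normal library held out, 78.0% to 91.9% of genes called without them kept the sign. Among the 171 named genes, 0 changed sign with a call in the main or the alternative fit. Genes called in neither did change sign, such as Cux2 (log2 fold change −0.634 to 3.05) and Cxcl10 (−1.20 to 4.14). The cause of the shifts in the counts was not tested.

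Hbegf did not pass in any of the 20 alternatives, with log2 fold changes of 0.64 (without restricted 5) to 2.10 (Kdm5d as a covariate) and adjusted p of 0.0750 to 0.519. It had only 4 to 56 counts per library, and how far depth limited the precision was not tested.

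The number of lists past adjusted p was 0 with an estimated correlation and 4 with fry, against 9, and it was 8 to 10 with each library left out and in the other alternatives at the preset correlation. With an estimated correlation it was 0 also with Kdm5d as a covariate, in both subsets of libraries and with each library left out. At an unadjusted p, camera called 3 lists with the estimated correlation and 12 with the preset one. Among lists, the mean log2 fold change of the interferon response was −1.10 with restricted 1, 3 and 4 alone (adjusted p 1.59e-05), against 1.11 with all libraries, and the list was called higher with Kdm5d as a covariate (adjusted p 1.57e-06). That covariate also added the calls of the growth hormone and IGF axis (0.0381, lower), gluconeogenesis and glycogen (0.0427, lower) and immediate early genes (5.75e-08, higher). It ended those of glycolysis (0.179) and oxidative phosphorylation (0.0819). The diet change in that fit rests mainly on restricted 5, the only restricted library with Kdm5d counts. Median log2 fold changes with the covariate and in restricted 5 against the normal libraries were −0.517 and −0.521 for the growth hormone and IGF axis. They were −0.112 and −0.112 for gluconeogenesis and glycogen, and 1.94 and 1.91 for immediate early genes. For erythroid markers the test turned to lower with Kdm5d as a covariate (mean 0.0124, adjusted p 0.840) and in the 6 libraries with Kdm5d counts (mean 0.0391, adjusted p 0.738). The periportal minus pericentral difference was 0.131 with medians over list members (exact permutation p 0.651), and ran from −0.218 to 0.0139 with each library left out, the latter without restricted 2; the block gave an exact sign-flip permutation p of 0.75, where the smallest possible is 0.0625. The cause of the other shifts was not tested.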

Other observations

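The list tests and the fits that left out a library were planned, and Kdm5d as a covariate in the list tests, and an estimated correlation in the list tests of these fits, were chosen after the data were seen.

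Among amino acid, one-carbon and detoxification genes, single members passed, and camera did not call their lists with all libraries. Of 21 tested genes of the urea cycle and amino acid catabolism, 2 rose and 1 fell, also 2 and 1 when adjusted over the list alone (camera adjusted p 0.460). Asl, of the urea cycle, had 258 ± 41.5 and 443 ± 139 CPM (SD, n = 5; adjusted p 0.0408, up to 0.0930 without normal 4, passing only without restricted 1 or 5), and Bckdhb changed by −0.56 ± 0.12 (log2, SE; adjusted p 0.0206, and 0.0581 without normal 5). Of 18 one-carbon and DNA methylation genes, 1 rose and 1 fell, or 2 and 1 when adjusted over the list alone (adjusted p 0.399). Shmt2, which feeds serine into one-carbon metabolism, fell from 193 ± 15.2 to 119 ± 17.4 CPM (adjusted p 0.0077). Of 17 xenobiotic genes, 1 rose and 1 fell, or 3 and 1 when adjusted over the list alone (adjusted p 0.138, and 0.0436 for xenobiotic metabolism without normal 2, or 0.397 there with an estimated correlation), and Gstm1, a glutathione transferase, changed by −0.87 ± 0.15 (log2, SE; adjusted p 0.0088). Of 20 bile acid genes, 1 rose, also 1 when adjusted over the list alone (adjusted p 0.542). It was Abcb4, the phospholipid transporter of bile, with 133 ± 39.3 and 262 ± 55.7 CPM (adjusted p 0.0231, and up to 0.0632 without normal 5, also lost without normal 3 or 4), while Cyp7a1, which starts bile acid synthesis, had a log2 fold change of −2.01 ± 0.88 (adjusted p 0.249).

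Lipid storage and stress genes also included single changes. Of 20 lipoprotein and lipid uptake genes, 2 rose and 1 fell, or 5 and 2 when adjusted over the list alone (adjusted p 0.165), and Plin2, a coat protein of lipid droplets, rose from 203 ± 37.5 to 488 ± 171 CPM (SD, n = 5; adjusted p 0.0117, and 0.0641 with the replicate number as a block). Of 16 unfolded protein and amino acid response genes, 1 rose, or 2 rose and 1 fell when adjusted over the list alone (adjusted p 0.965); their median was −0.03 and their mean 0.10. Herpud1, of protein disposal in the endoplasmic reticulum, rose from 142 ± 30.2 to 256 ± 35.7 CPM (adjusted p 0.00888). Of 15 insulin signalling genes, Trib3, an inhibitor of AKT, alone passed, also alone when adjusted over the list alone (log2 fold change 1.54 ± 0.32, adjusted p 0.0274, list 0.173), and it had 0.0730 without normal 4 and also missed the threshold without normal 2, 3 or 5 or restricted 2 or 4. Of 11 immediate early genes, Gadd45b alone passed, also alone when adjusted over the list alone (list adjusted p 0.125), and the list score was 2.11 in restricted 5. With Kdm5d as a covariate this list, the immediate early and handling response, was called higher (adjusted p 5.75e-08, median log2 fold change 1.94) with 2 members past the test, and it also passed without restricted 2 (0.00272), but with an estimated correlation these were 0.233 and 0.607. Of 2 tested acinar markers of pancreas, Cpb1, a carboxypeptidase, had 0.776 ± 0.275 and 3.50 ± 1.85 CPM (adjusted p 0.00854), and both passed when adjusted over the list alone.

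The remaining lists had 0 members past the edgeR test. MAPK feedback genes had 0 of 13, 0 when adjusted over the list alone, 2 at unadjusted p and 0 in DESeq2 and limma-voom (camera adjusted p 0.337). Acute phase genes had 0 of 14, 1 higher and 1 lower when adjusted over the list alone and in DESeq2, 5 at unadjusted p and 0 in limma-voom (0.337). Fetal and neonatal liver genes had 0 of 10, 0 when adjusted over the list alone, 1 at unadjusted p and 0 in DESeq2 and limma-voom (0.399), and Afp had a log2 fold change of −0.51 ± 0.24 (adjusted p 0.255). The male-biased adult rat liver genes had 0 of 6, 0 when adjusted over the list alone, 2 at unadjusted p, 1 higher and 1 lower in DESeq2 and 1 lower in limma-voom (0.165, and 0.00185 without restricted 5, or 0.436 there with an estimated correlation). The female-biased adult rat liver genes had 0 of 6, 2 higher when adjusted over the list alone and in DESeq2, 2 at unadjusted p and 0 in limma-voom (0.108, and 0.00132 without restricted 5 and 0.0406 without normal 4, or 0.436 and 0.597 there with an estimated correlation). Stellate cell and matrix genes had 0 of 16, 0 when adjusted over the list alone, 4 at unadjusted p and 0 in DESeq2 and limma-voom (0.399), with a median of −0.05 and a mean of 0.00. Cholangiocyte markers had 0 of 10, 2 higher and 1 lower when adjusted over the list alone, 4 at unadjusted p, 1 higher in DESeq2 and 0 in limma-voom (0.391). Neutrophil markers had 0 of 8 and adipose markers 0 of 4, with 0 when adjusted over the list alone, 1 at unadjusted p and 0 in DESeq2 and limma-voom for each (0.399 and 0.433). The list of Y-linked genes had 1 tested member and that of skeletal muscle 1, too few for a list test, with 0 past edgeR. Limma-voom called the Y-linked member, Kdm5d, lower.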
